A study of Homo sapiens with 16 samples.

How the data were processed

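Messenger RNA was measured by sequencing in 16 cultures of BEAS-2B, an immortalized human bronchial epithelial cell line. Per the labels, there were 4 groups of 4: untreated (Control), given HDM, given microvesicles from alveolar macrophages (MV), and given both (HDM+MV). They give 3 h of treatment for HDM, MV and HDM+MV and no time for Control. The labels do not spell out HDM, which in airway research stands for house dust mite. They also leave open the species that the macrophages came from, the doses, and the meaning of the replicate numbers 2, 20, 21 and 28, which recur in every group. Libraries are named here by group and number, as in HDM 20. Per the labels, RNA was extracted with either of 2 kits, and which library had which kit is not recorded, so the kit could not enter any comparison.

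The deposited table of raw counts holds whole numbers of fragments per gene, with no normalization. Per the file headers, featureCounts 1.5.0 counted pairs with both ends mapped over the exons of each gene, without strand, without multi-mapped reads and without reads shared by overlapping genes. Alignment used TopHat2 2.0.7 to hg19, per the submitters' processing notes. The second deposited table is a signal, normalized counts per gene made by the authors by dividing each library's counts by a single size factor. Multiplying back gave whole reads for 100% of its values (tolerance 1e-05), and its factors, 0.768 to 1.17, equalled those of DESeq2 in 16 of 16 libraries within 1e-06. The processing notes name DESeq2 1.10.1 and DESeq without saying which made it. This table was used only for an alternative test.

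The count table had 25370 entries. The 1 entry without a gene name held 0 counts and was left out, which left 25369 genes, 5702 of them at 0 in every library. It lists 0 mitochondrially encoded genes. Low counts were filtered with edgeR's filterByExpr (minimum count 10, about 0.552 CPM, and minimum total 15), which kept 13419 genes. Total counts ran from 14112654 to 21355805 per library. Between replicates of a group, counts varied 6.19 to 66.2 times as much as counting error alone would give (chi-square per degree of freedom). The median standard error of a log2 fold change was 0.121 to 0.122 between groups and 0.172 for the interaction.

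Counts were scaled by TMM and tested with edgeR's quasi-likelihood F test (R 4.3.3, edgeR 4.0.16), with all 16 libraries in a single fit of 4 group means and 12 residual degrees of freedom. There were 6 comparisons: HDM, MV and HDM+MV each against Control, HDM+MV against HDM, HDM+MV against MV, and the interaction, which is the HDM effect with microvesicles minus the HDM effect without them. Genes with a Benjamini-Hochberg adjusted p below 0.05 are said to have risen or fallen, and adjusted p-values of genes below come from this test unless another is named. Levels are CPM (edgeR's cpm on TMM-scaled totals), as mean ± SD of the 4 libraries of a group. Fold changes are given with their standard errors. P-values measure only the spread between these samples, which may be partly technical.

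The comparisons, the alternatives, 32 gene lists and the rule for naming genes were fixed before the data were examined. The rule took, in each comparison, the 8 largest rises and the 8 largest falls among genes with an adjusted p below 0.05 and at least 2 CPM in the higher group, and the 6 others with the smallest adjusted p. Where fewer than 5 genes passed, it took the 5 with the smallest p. It added the sentinel genes CXCL8, IL6, CCL20, CSF2, CXCL1, TNFAIP3, TSLP, IL33, IL1B, PTGS2, IGF1R and RAC1, and up to 4 members of each list described. IL33 had too few counts to be tested. Lists were tested with camera (limma 3.58.1), which asks whether a list's genes moved differently from all other genes, with a preset correlation of 0.01 between genes and adjustment over the 28 lists with at least 5 measured members. A camera call is given with its adjusted p under a correlation estimated from the data where that ended the call, and the number of members that passed is given over all genes and adjusted over the list alone.

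The replicate numbers were checked for pairing. Across genes, the deviations of same-numbered libraries from their group means correlated in all 24 pairs (Pearson r 0.365 to 0.822, mean 0.552), against a mean of -0.172 over the 72 other pairs, and genes are not independent replicates. The numbers therefore pair the samples, as shown by the data and not by the labels. Of the 16 libraries, 14 correlated best with their own number, and the exceptions were MV 20 and MV 21. The fit with the replicate number as a block was listed beforehand as an alternative. It is given beside results whose call it changed, and where it moved the number of genes called in a comparison by more than 1.5 times. The counts of list members that passed are given without the block only, so they can be lower than with it. Its median standard errors were 0.0739 to 0.075 between groups and 0.105 for the interaction.

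The other alternatives were DESeq2 size factors, the DESeq2 Wald test (DESeq2 1.42.0) with and without the block, limma-voom, and limma on log2 of the deposited normalized counts plus 1. Further ones were no filter, a filter of 1 CPM in 4 libraries, a fit of only the groups compared, fry for the lists, and leaving out each library in turn. The fits with a single library left out had no block, so the same-numbered libraries of the other groups lost their partner. Alternatives added later exchanged the numbers of MV 20 and MV 21 within the block, left out the 4 libraries numbered 2, or left out MV 20 and MV 21. The edgeR fits without and with the block were tested on simulated counts of 13419 genes with 50 genes planted per fold size. The interaction, DESeq2, limma-voom and fry were not simulated. For HDM against control the fit without the block recovered 16% of 1.3-fold, 54% of 1.5-fold, 72% of 2-fold and 96% of 4-fold changes. For MV against control it recovered 14%, 38%, 86% and 96%. For HDM+MV against HDM it recovered 20%, 52%, 64% and 92%. With the block it recovered 56%, 70%, 98% and 98% for HDM against control, 66%, 78%, 96% and 100% for MV against control, and 58%, 82%, 96% and 100% for HDM+MV against HDM, with 6, 12 and 10 false calls against 0, 1 and 0 without. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

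Because multi-mapped reads were dropped and strand was not used, genes with near-identical copies (HSPA1A and HSPA1B, the metallothioneins) and genes whose exons overlap are uncertain. The 69 genes checked were named by the rule or, like RGMB, chosen after their values were seen. Of these, 7 share exon sequence with another gene. Among them are FGF2 (with NUDT6, 70.7 against 1.2 mean CPM), RGMB (with RGMB-AS1, 90.1 against 1.3) and TNFAIP6 (with LOC101929319, 7.82 against 0.0111). C15orf61 and IQCH-AS1 had like levels (1.87 and 2.14 CPM), so reads of C15orf61 could not be told from those of its partner.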

Results

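Gene expression was measured by mRNA sequencing in BEAS-2B bronchial epithelial cells, in 4 libraries per group. The cells had HDM, macrophage microvesicles or both for 3 h, or were untreated, with no time given. The question, as the study's title states it, concerns how macrophages influence the inflammation of cells that are not professional phagocytes. Total counts of Control 2, 20, 21 and 28 were 17327393, 21355805, 19396965 and 17701432, and those of HDM were 19651872, 14112654, 15650052 and 19533393. In the same order, MV libraries had 17465639, 19545358, 20149203 and 19407576 counts, and HDM+MV libraries 17822803, 18424973, 17499108 and 16895119.

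**Figure D1:**
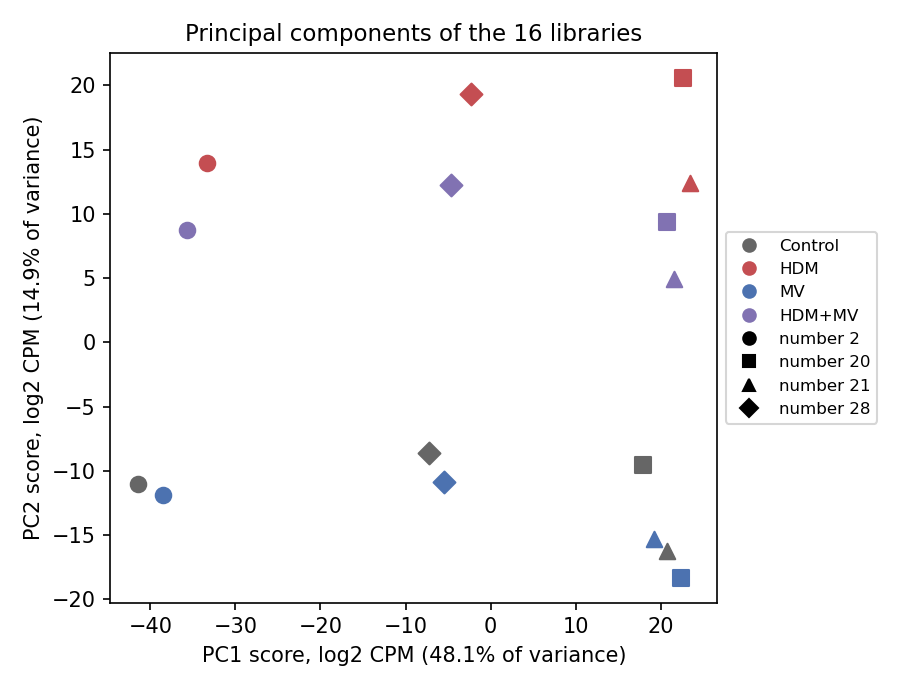
Scores of the 16 libraries on the first and second principal components of log2 CPM, coloured by group and shaped by replicate number. The first axis (48.1% of variance) follows the replicate number, with number 2 at one end and 20 and 21 at the other, and on the second (14.9%) the 8 libraries with HDM lie above the 8 without.

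HDM against control shows what HDM did alone. Cytokines and chemokines that call in immune cells rose: CXCL8, which attracts neutrophils, went from 22.4 ± 8.19 to 201.6 ± 23 CPM (9.01-fold, n = 4). CCL20, which attracts dendritic and lymphoid cells, rose 9.30-fold and IL6 8.15-fold. Of the genes that restrain this response, TNFAIP3 rose 6.02-fold, from 23.3 ± 7.84 to 140.4 ± 37.2 CPM, and NFKBIA 2.76-fold. Of 31 interferon-stimulated genes 11 rose: IFIT2 rose 39.96-fold, from 6.25 ± 1.32 to 249.9 ± 133 CPM, CXCL10 50.2-fold and IFIT3 14.2-fold. The pattern recognition protein PTX3 rose from 27.6 ± 8.38 to 200.5 ± 14 CPM, and the adhesion molecule ICAM1 from 104.3 ± 11.8 to 265.9 ± 14.8 CPM. The glucocorticoid-induced gene TSC22D3 fell by 0.66 on the log2 scale, from a mean of 34.7 CPM in Control, and the clock gene PER1 fell by 0.57.

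In the edgeR quasi-likelihood test, with Benjamini-Hochberg adjustment over 13419 genes, 124 genes passed for HDM against control, 115 up and 9 down. The count was 848 with the replicate block, 623 up and 225 down, including all 124. By this test the log2 fold change was 3.17 ± 0.34 for CXCL8 (hg19 chromosome 4, 74606223 to 74609433; adjusted p = 0.00016), 3.22 ± 0.31 for CCL20 (chromosome 2, 228678558 to 228682280; adjusted p = 8.06e-05) and 3.03 ± 0.46 for IL6 (chromosome 7, 22766766 to 22771621; adjusted p = 0.00272). It was 2.86 ± 0.20 for PTX3 (chromosome 3, 157154580 to 157161417) and 1.47 ± 0.10 for NFKBIA (chromosome 14, 35870716 to 35873960), both with an adjusted p of 2.98e-06. IFIT2 (chromosome 10, 91061706 to 91069033) rose by 5.32 ± 0.72 (edgeR adjusted p = 0.00104) and CXCL10 (chromosome 4, 76942269 to 76944689) by 5.65 ± 0.90 (adjusted p = 0.00397). TNFAIP3 (chromosome 6, 138188325 to 138204451) rose by 2.59 ± 0.30 (edgeR adjusted p = 0.000267) and ICAM1 (chromosome 19, 10381517 to 10397291) by 1.35 ± 0.10 (adjusted p = 3.8e-06). By the same edgeR test IFIT3 rose by 3.83 ± 0.54 (adjusted p = 0.0015) and CXCL1 by 2.51 ± 0.36 (adjusted p = 0.00166). TSC22D3 (chromosome X, 106956452 to 107019017) fell by 0.66 ± 0.10 (edgeR adjusted p = 0.00292). Of the 27 called genes that the rule took by size, by p or as sentinels, 27 moved the same way in all 4 numbers. The sentinels IL1B (1.93 ± 0.59, adjusted p = 0.223) and PTGS2 (1.01 ± 0.49, adjusted p = 0.675) passed in the edgeR fit only with the block (adjusted p = 2.6e-07 and 0.00211). TSLP (0.49 ± 0.49, adjusted p = 1), IGF1R (0.25 ± 0.10, adjusted p = 0.542) and RAC1 (0.01 ± 0.06, adjusted p = 1) did not pass in the same edgeR test.

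**Figure D2:**
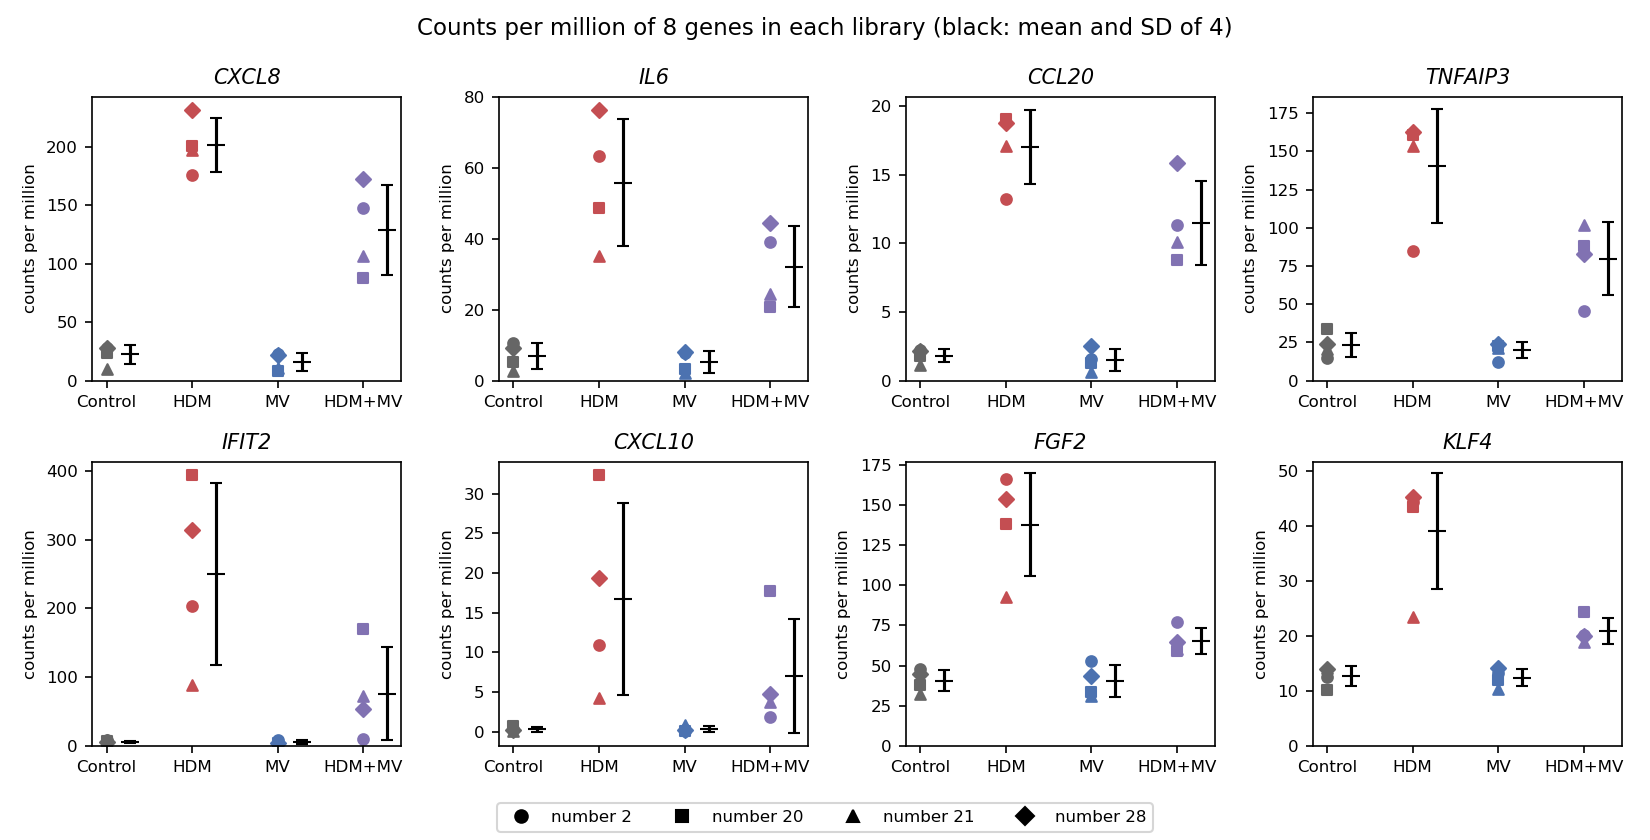
CPM of 8 genes in each of the 16 libraries, shaped by replicate number, with the mean and SD of each group in black. CXCL8, IL6, CCL20 and TNFAIP3 are higher in every library with HDM than in every library without, and FGF2 and KLF4 are lower in HDM+MV than in HDM on average.

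Among the fixed lists, NF-kB feedback genes and targets had the smallest p: 16 of 23 rose, 21 adjusted over the list alone, with a median log2 fold change of 1.1 (camera adjusted p = 5.43e-141). Among them were TNFAIP2 (1.60 ± 0.12), ZC3H12A (1.42 ± 0.14) and NFKB1 (0.85 ± 0.08). Inflammatory cytokines and chemokines followed, with 11 of 27 up, 18 adjusted over the list alone, and a larger median of 1.93 (camera adjusted p = 3.42e-58). They included CXCL2 (2.44 ± 0.24), CXCL3 (2.59 ± 0.36) and CCL2 (2.18 ± 0.28). Of 31 interferon-stimulated genes, 11 rose, 17 adjusted over the list alone, including IRF1 (1.5 ± 0.19) and the RNA sensor DDX58 (2.65 ± 0.38), at a median of 0.61 (camera adjusted p = 5.47e-31). This call held with an estimated correlation (adjusted p = 0.0106) but not with that and the replicate block together (adjusted p = 0.0832). Immediate early genes had 5 of 22 up, 8 adjusted over the list alone, with KLF4 (1.62 ± 0.18), KLF6 (0.45 ± 0.07) and ATF3 (1.09 ± 0.18), at a median of 0.47 (camera adjusted p = 2.19e-14). Of 15 cytokine signalling brakes, ZC3H12A, TNFAIP3 and TNIP1 rose and TSC22D3 fell, with 5 up and 1 down adjusted over the list alone, at a median of 0.04 (camera adjusted p = 2.23e-08). Of 21 p53 targets, 3 rose, including PMAIP1 (2.02 ± 0.24) and TNFRSF10B (0.48 ± 0.08), with 6 up and 1 down adjusted over the list alone, at a median of 0.08 (camera adjusted p = 0.000267). The calls of these 6 lists held with an estimated correlation.

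Another 6 lists passed camera only at the preset correlation. Of 22 EGFR ligands and feedback genes, 3 rose, 4 adjusted over the list alone, with EREG (1.09 ± 0.15) and HBEGF (1.48 ± 0.27) (camera adjusted p = 5.6e-05, adjusted p = 0.114 with an estimated correlation). Of 20 oxidative stress genes, SLC7A11 (0.42 ± 0.06) rose, 1 adjusted over the list alone (camera adjusted p = 0.00791, 0.298 with an estimated correlation). Of 12 heat shock genes 0 passed, 0 adjusted over the list alone (camera adjusted p = 0.00715, 0.234 with an estimated correlation). Of 5 measured alarmins and type 2 cytokines, CSF2 rose, 1 adjusted over the list alone (camera adjusted p = 0.0203, 0.0719 with an estimated correlation, 0.0146 with that and the replicate block). Of 11 prostaglandin genes 1 rose, 1 adjusted over the list alone (camera adjusted p = 0.0343, 0.0877 with an estimated correlation, 0.0371 with that and the block). The 36 ribosomal proteins were lower by a median of -0.04 (camera adjusted p = 0.0343, 0.764 with an estimated correlation) with 0 members passing. The remaining 16 lists did not pass camera. Their adjusted p was 0.65 for phagocytosis and engulfment, 0.792 for glucocorticoid-responsive genes, 0.142 for unfolded protein response and ATF4 targets, 0.58 for cholesterol synthesis, 0.648 for cholesterol efflux and 0.947 for IGF signalling. For hypoxia and glycolysis it was 0.856, metallothioneins 0.989, cell cycle 0.102, TGF-beta targets 0.35, actin cytoskeleton 0.166, epithelial junctions 0.253, lysosome 0.65, histones 0.272, macrophage markers 0.985, and fibroblast and endothelial markers 0.35. With the block, cell cycle (adjusted p = 0.0327, 0.285 with an estimated correlation) and actin genes (0.0428 and 0.197) passed as lower. Lymphocyte markers had 2 measured members, and granulocyte, red cell and mitochondrially encoded lists 0, so these were not tested.

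Some of these HDM calls ended when single libraries were left out, at fold changes near those of the full fit. The fits had no replicate block, and leaving out single libraries was not tested with it. Whether the calls depend on single libraries once the numbers are paired is therefore not known. Libraries outside the comparison entered through the shared fit. IRG1, which encodes the enzyme that makes itaconate, had the largest fold of the named genes (5.88 ± 1.17, edgeR adjusted p = 0.0204, from 0.0646 ± 0.0646 to 4.33 ± 4.41 CPM). It lost its call without Control 2 (0.0772), 20 (0.0838), 21 (0.0682) or 28 (0.0888) or HDM 20 (0.0647). CSF2 (2.50 ± 0.55, edgeR adjusted p = 0.0429) lost its call when any of 12 libraries was left out, all except Control 20, HDM 2, MV 2 and HDM+MV 2 (adjusted p = 0.0547 to 0.155). PER1 (-0.57 ± 0.12, edgeR adjusted p = 0.0381) lost it without Control 20, 21 or 28, any HDM library, MV 21 or 28, or HDM+MV 20 (adjusted p = 0.0535 to 0.144). The prostaglandin gene that rose, PTGER4, lost its edgeR call without any Control or MV library, HDM 20 or 28, or HDM+MV 20 or 21 (adjusted p = 0.0501 to 0.162), which leaves 0 of that list. Of the p53 targets PLK2 lost it without Control 20 (0.0528), 21 (0.0739) or 28 (0.0779) or HDM 2 (0.0541) or 28 (0.0681), and of the immediate early genes NR4A3 without Control 21 (0.0739) or 28 (0.0717) or HDM 20 (0.0591). IER3, in the NF-kB and EGFR lists, lost it without Control 2, 20 or 21 or HDM 20, 21 or 28 (0.0575 to 0.117). In these fits the log2 fold change was 4.90 to 6.66 for IRG1, 2.16 to 2.57 for CSF2, -0.62 to -0.48 for PER1, 0.76 to 0.98 for PTGER4, 0.70 to 0.83 for PLK2, 1.87 to 2.02 for NR4A3 and 0.57 to 0.71 for IER3. All 7 passed in edgeR with the replicate block (adjusted p = 1.05e-07 for CSF2 to 0.00242 for NR4A3). Camera's call ended for alarmins without HDM 20 (0.0961) and for prostaglandin genes without Control 2 (0.11), HDM 20 (0.0961) or HDM 28 (0.0862). It also ended for oxidative stress genes without Control 21 (0.0588), HDM 2 (0.0839) or HDM 28 (0.0597), and for ribosomal proteins without Control 2 (0.177), Control 28 (0.518), HDM 20 (0.132) or HDM 21 (0.68).

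MV against control shows what microvesicles did alone. No cytokine changed past the threshold: CXCL8 was 22.4 ± 8.19 CPM in Control and 16.0 ± 7.28 in MV (log2 fold change -0.49 ± 0.33, n = 4, adjusted p = 1 in the edgeR test), lower in 3 of 4 numbers. CXCL1 (-0.54 ± 0.35) and CCL20 (-0.28 ± 0.34) were likewise lower in 3 of 4. IL6 (-0.37 ± 0.47) was lower in all 4, as was PTGS2, and did not pass. TNFAIP3 (-0.21 ± 0.29), the growth factor receptor gene IGF1R (-0.05 ± 0.10) and RAC1 (-0.03 ± 0.06), which drives engulfment, did not pass either. The 5 genes with the smallest p were CCDC7 (-0.67 ± 0.18), LINC01123 (-0.38 ± 0.12), C15orf61 (0.53 ± 0.17), TBC1D22B (-0.205 ± 0.07) and ERCC3 (-0.13 ± 0.05), all with an adjusted p of 1. Genes of phagocytosis and engulfment as a list did not pass (camera adjusted p = 0.991).

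Inflammatory lists stood lower in MV than in Control by small margins. Of 27 inflammatory cytokines and chemokines, 21 had negative log2 fold changes, at a median of -0.15 (camera adjusted p = 2.9e-05, adjusted p = 0.101 with an estimated correlation, 0.0053 with that and the replicate block). NF-kB targets had a median of -0.10 (camera adjusted p = 5.09e-07, 0.0801 with an estimated correlation). Immediate early genes (median -0.07, camera adjusted p = 0.00032, 0.101 with an estimated correlation) and interferon-stimulated genes (median -0.06, camera adjusted p = 0.000848, 0.664 with an estimated correlation) were lower as well. EGFR feedback genes (-0.05, camera adjusted p = 0.0438, 0.664 with an estimated correlation), glucocorticoid-responsive genes (-0.08, 0.0331 and 0.101, the second 0.0402 with the block), metallothioneins (-0.08, 0.0331 and 0.231) and ribosomal proteins (-0.03, 0.017 and 0.767) completed the 8 lists. In each of the 8, 0 members passed, and 0 adjusted over the list alone. With the block, actin genes passed as higher (camera adjusted p = 0.00319, 0.118 with an estimated correlation) and signalling brakes as lower (0.0341 and 0.118). The fry test called 0 of the lists in this comparison without the block.

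The edgeR test called 0 genes for MV against control, with and without the replicate block, and 47 genes had an unadjusted p under 0.05 (221 with the block). The DESeq2 Wald test, limma-voom and limma on the normalized counts also called 0, and DESeq2 with the block called 1, BAI1, chosen after its values were seen, at a count too low for the edgeR filter. Only the NF-kB list kept its camera call whichever library was left out. The call ended without Control 20 (0.0769) or MV 2 (0.153) for the inflammatory list, without Control 28 (0.117) or MV 2 (0.419) for immediate early genes, and without Control 2 (0.649, with the direction turned) or MV 20 (0.25) for interferon-stimulated genes. Without Control 28 (0.313 to 0.992) or MV 2 (0.201 to 0.977) it ended for each of the other 4 lists, and the direction turned for EGFR genes without MV 2 (0.977) and for ribosomal proteins without Control 28 (0.992). It ended also for EGFR genes without Control 20 or 21, HDM 20 or 21, MV 21 or HDM+MV 2, 21 or 28, and for glucocorticoid-responsive genes without Control 2 or 20 or MV 20 or 21. The same held for metallothioneins without Control 21 or MV 20, and for ribosomal proteins without Control 2 or MV 20.

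HDM+MV against control shows what both agents did together. Several of the chemokines and NF-kB genes that HDM raised alone were also raised here: CXCL8 went from 22.4 ± 8.19 to 128.5 ± 38.5 CPM (5.74-fold, n = 4). CCL20 rose 6.28-fold and PTX3 4.53-fold, and TNFAIP3 went from 23.3 ± 7.84 to 79.6 ± 23.8 CPM. TNFAIP6, whose product binds hyaluronan, rose from 2.25 to 13.1 mean CPM. In the fit without the replicate block, IFIT2 was the only interferon-stimulated gene that passed, at 12.2-fold. IL6 reached 32.2 ± 11.5 CPM, and edgeR with all 16 libraries called it only with the replicate block. The DESeq2 Wald test and the edgeR fit without MV 21 called it as well.

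By edgeR's quasi-likelihood test, CXCL8 rose by 2.52 ± 0.34 (log2, adjusted p = 0.00282) and CCL20 by 2.65 ± 0.31 (adjusted p = 0.00061). By the same edgeR test, PTX3 rose by 2.18 ± 0.19 (adjusted p = 6.59e-05), ICAM1 by 1.11 ± 0.10 (adjusted p = 6.68e-05) and NFKBIA by 1.07 ± 0.10 (adjusted p = 0.000102). TNFAIP6 (chromosome 2, 152214106 to 152236562) rose by 2.56 ± 0.44 (edgeR adjusted p = 0.0186) and the glycosyltransferase gene B4GALT5 by 0.39 ± 0.05 (adjusted p = 0.00327). IL6 was higher by 2.23 ± 0.45 (edgeR adjusted p = 0.0565, and 1.81e-07 with the replicate block), and CSF2 (adjusted p = 0.604, 5.8e-05 with the block), IL1B (0.855 and 4.5e-06) and KLF4 (0.217 and 0.0163) also passed only with the block when all 16 libraries were kept. The test called 34 genes, 34 up and 0 down, and 356 with the block, 293 up and 63 down. Without the block 565 genes had an unadjusted p under 0.05 in either direction, and the DESeq2 Wald test called 95 genes and limma-voom 33. All 15 called genes that the rule took by size, by p or as sentinels rose in all 4 numbers. The rise of IFIT2 was small in number 2, with 7.97 CPM in Control and 9.36 in HDM+MV, against 6.62 and 169.3 in number 20.

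Of the NF-kB list, 13 of 23 rose with HDM+MV, 21 adjusted over the list alone, at a median of 0.88 (camera adjusted p = 8.87e-142), with TNFAIP2 (1.32 ± 0.12), ZC3H12A (1.24 ± 0.14) and TNIP1 (0.88 ± 0.13). Of the inflammatory list, 6 of 27 rose, 17 adjusted over the list alone, at a median of 1.56 (camera adjusted p = 3.19e-56), with CXCL2 (2.08 ± 0.24) and CXCL1 (2.16 ± 0.35). Signalling brakes had 3 up, 4 up and 1 down adjusted over the list alone (camera adjusted p = 1.46e-08). Alarmins (0 passing, 1 adjusted over the list alone, camera adjusted p = 0.00145), p53 targets (0 and 2, 0.00074) and immediate early genes (0 and 3, 7.3e-05) also passed. All 6 calls held with an estimated correlation, that of immediate early genes at 0.0423 and, with the replicate block as well, no longer (0.103). With preset correlation only, interferon-stimulated genes (1 passing, 11 adjusted over the list alone, median 0.28, camera adjusted p = 3.48e-17, 0.0572 with an estimated correlation) were higher. EGFR feedback genes with EREG (1 and 5, 2.04e-06 and 0.0629) and oxidative stress genes with SLC7A11 (1 and 1, 0.000106 and 0.112, and 0.0282 with that and the block) were higher too. Unfolded protein response genes (0 and 1, 0.0104 and 0.315), heat shock genes (0 and 0, 0.00663 and 0.215) and epithelial junctions (0 and 0, 0.0394 and 0.602) were also called higher. Actin genes were lower by a median of -0.07 (camera adjusted p = 0.000804, 0.196 with an estimated correlation, 0.0175 with that and the block), as were ribosomal proteins (-0.06, 0.000165 and 0.512) and cell cycle genes (0.0256 and 0.529), each with 0 members passing and 0 adjusted over the list alone. With the block, prostaglandin genes passed as higher (0.0164, 0.0818 with an estimated correlation) and TGF-beta targets as lower (0.0296 and 0.381).

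Some HDM+MV calls ended when single libraries were left out, in fits without the replicate block. IFIT2 (3.61 ± 0.68, edgeR adjusted p = 0.0359) lost its call without any Control library, HDM 2 or 28, MV 20, 21 or 28, or HDM+MV 20, 21 or 28 (adjusted p = 0.0534 to 0.171), and TNFAIP6 without Control 20 (0.0859), Control 21 (0.0765) or HDM+MV 28 (0.0807). CXCL1 (edgeR adjusted p = 0.0111) lost it without HDM+MV 28 (0.051), CXCL3 without Control 2, 21 or 28, HDM 20, MV 21, or HDM+MV 20, 21 or 28 (0.0513 to 0.138), and TNFAIP3 (1.77 ± 0.29, edgeR adjusted p = 0.0124) without Control 21 (0.0765), Control 28 (0.0611) or HDM+MV 21 (0.0546). In these fits the log2 fold change was 2.84 to 3.74 for IFIT2, 2.25 to 2.43 for TNFAIP6, 1.99 for CXCL1, 1.71 to 2.06 for CXCL3 and 1.63 to 1.78 for TNFAIP3, and all 5 passed in edgeR with the block (adjusted p = 3.1e-08 for TNFAIP3 to 0.0021 for IFIT2). Camera calls ended for unfolded protein response genes without Control 2 (0.226), Control 20 (0.0627) or HDM+MV 2 (0.198), and heat shock genes without Control 2 (0.0648) or 20 (0.0866). They ended for ribosomal proteins without Control 28 (0.0546), junctions without Control 2 (0.995), Control 28 (0.324), HDM+MV 20 (0.691) or 21 (0.326), and cell cycle genes without the same 4 libraries (0.0834 to 0.511).

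HDM+MV against HDM asks whether microvesicles altered expression in cells that also had HDM. The growth factor gene FGF2 was 137.7 ± 32.2 CPM with HDM and 65.3 ± 8.23 with both (n = 4), against 40.7 ± 6.75 in Control, and lay lower in all 4 numbers. It did not pass the test without the replicate block and passed with it. KLF4 and KLF6, transcription factor genes that respond early to stimuli, PMAIP1, whose product promotes cell death, and the deadenylase gene CCRN4L were lower in the same way. TNFAIP3 was 140.4 ± 37.2 CPM with HDM and 79.6 ± 23.8 with both, and IL6 55.9 ± 17.9 and 32.2 ± 11.5 CPM. CXCL8 (-0.65 ± 0.31), CCL20 and CXCL1 were also lower in all 4 numbers but did not pass in either fit.

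By edgeR, FGF2 (chromosome 4, 123747863 to 123819390) differed by -1.08 ± 0.19 (adjusted p = 0.577), and by -1.06 ± 0.08 with the replicate block (adjusted p = 4.43e-06). KLF4 (-0.91 ± 0.18, edgeR adjusted p = 0.598, 0.0102 with the block), KLF6 (-0.37 ± 0.07, 0.598 and 0.00558), CCRN4L (-0.84 ± 0.17, 0.598 and 0.0147) and PMAIP1 (-1.08 ± 0.24, 0.984 and 0.00688) were the other 4 with the smallest p. Sentinels that edgeR called only with the block were TNFAIP3 (-0.82 ± 0.28, adjusted p = 1 and 0.000467), IL6 (-0.80 ± 0.41, 0.0143 with the block), CSF2 (0.0386 with the block) and PTGS2 (0.0354 with the block, lower in 3 of 4 numbers). PTX3 (-0.68, 0.0386) and NFKBIA (-0.40, 0.0313) did likewise. Without the block edgeR called 0 genes, with 192 at an unadjusted p under 0.05, and limma-voom 0. The DESeq2 Wald test called 5, which were FGF2, KLF4, KLF6, CCRN4L and PMAIP1, and 44 with the block. With the block edgeR called 30 genes, 28 lower and 2 higher, the last being DDIT4 and TOB1, chosen after their values were seen. Without HDM 21 the fit with no block called 2 genes, KLF4 (-1.09, edgeR adjusted p = 0.00658) and FGF2 (-1.225, adjusted p = 0.0228).

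In HDM+MV against HDM, 3 of the lists raised by HDM alone were lower with microvesicles, and interferon-stimulated genes were so only at the preset correlation. NF-kB targets were lower in 22 of 23 members at a median of -0.23 (camera adjusted p = 6.31e-17), with 0 passing and 1 lower adjusted over the list alone. Immediate early genes were lower in 20 of 22 at a median of -0.19 (camera adjusted p = 3.99e-13), with 0 passing and 4 lower adjusted over the list alone. Inflammatory cytokines and chemokines were lower in 22 of 27 at a median of -0.38 (camera adjusted p = 1.94e-10), with 0 passing and 0 adjusted over the list alone. The counts of members passing in this paragraph are without the replicate block, with which TNFAIP3 and IL6, among others, passed as lower (above). The camera calls of these 3 lists held with an estimated correlation and whichever library was left out. They ended with the fry test (adjusted p = 0.0543 for NF-kB targets, 0.0543 for immediate early genes and 0.167 for the inflammatory list), and passed by fry with the block (0.0109, 0.0109 and 0.000795). Interferon-stimulated genes were lower in 25 of 31 at a median of -0.31 (camera adjusted p = 6.61e-19, 0.075 with an estimated correlation), with IFIT3 at -1.52 ± 0.48, and TGF-beta targets in 19 of 19 at -0.14 (5.4e-05 and 0.179), each with 0 passing and 0 adjusted over the list alone. Cholesterol efflux genes were higher by a median of 0.08 (0 and 0, camera adjusted p = 0.037, 0.179 with an estimated correlation), a call that ended without HDM 21 (0.117), HDM 28 (0.319), HDM+MV 20 (0.137) or HDM+MV 21 (0.285). With the block, signalling brakes (camera adjusted p = 0.00419, 0.0438 with an estimated correlation) and actin genes (0.0391 and 0.202) passed as lower. Genes of phagocytosis and engulfment did not pass (camera adjusted p = 0.575).

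**Figure D3:**
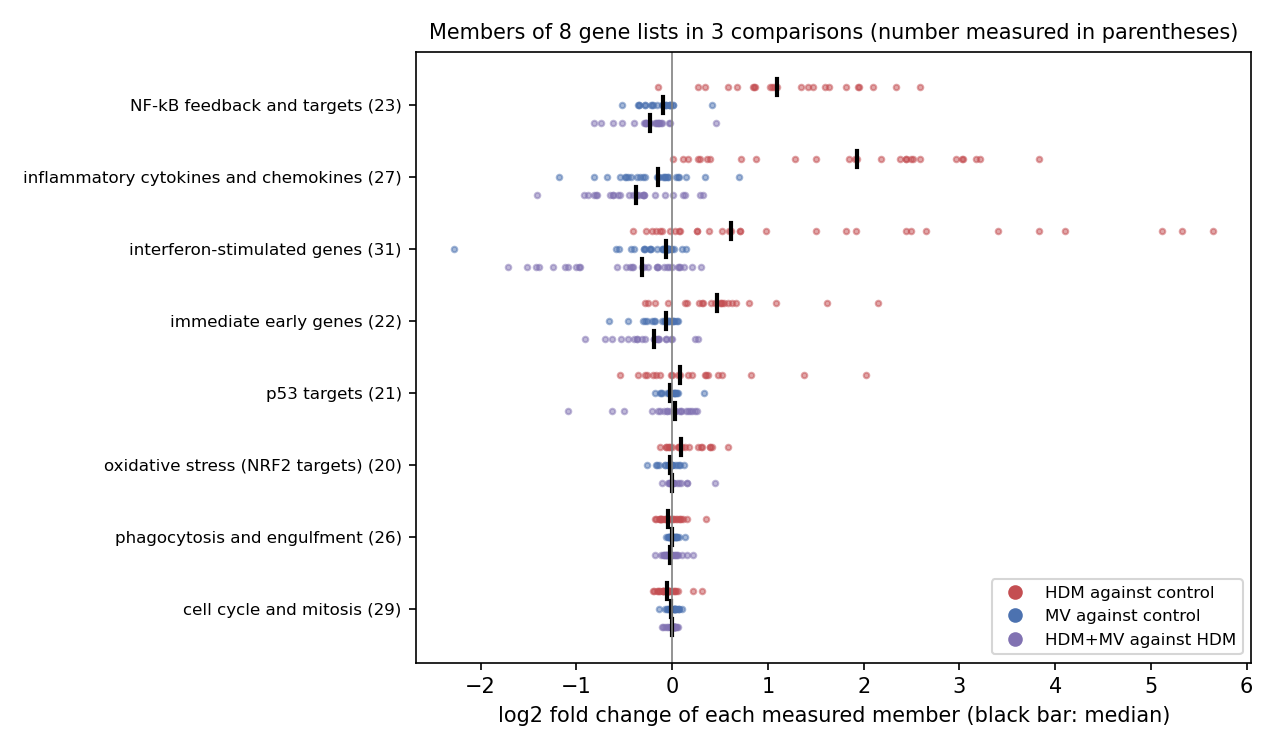
Log2 fold change of each measured member of 8 gene lists in 3 comparisons, with the median as a black bar. NF-kB, inflammatory, interferon-stimulated and immediate early genes lie mostly to the right of 0 with HDM against control and mostly to the left of 0 with HDM+MV against HDM, while phagocytosis and cell cycle genes lie near 0 in all 3.

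HDM+MV against MV gives the HDM effect in the presence of microvesicles. CXCL8 went from 16.0 ± 7.28 to 128.5 ± 38.5 CPM (8.06-fold, n = 4), and CCL20, CXCL1, CXCL3 and TNFAIP6 rose as well. IL6 went from 5.33 ± 3.07 to 32.2 ± 11.5 CPM, TNFAIP3 from 20.1 ± 5.18 to 79.6 ± 23.8 CPM, and PTX3 from 22.4 ± 3.1 to 125 ± 20.9 CPM. Interferon-stimulated IFIT2 went from 5.37 ± 2.62 to 76.1 ± 67.5 CPM. The only gene that fell, AXL, encodes a receptor kinase used to take up dying cells, and went from 387.6 ± 18.1 to 323.5 ± 19.4 CPM.

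In the edgeR test, CXCL8 rose by 3.01 ± 0.35 (log2, adjusted p = 0.000432) and CCL20 by 2.93 ± 0.31 (adjusted p = 0.000205). With edgeR, CXCL1 also rose by 2.70 ± 0.36 (adjusted p = 0.00178), TNFAIP6 by 2.97 ± 0.45 (adjusted p = 0.00507) and TNFAIP3 by 1.99 ± 0.30 (adjusted p = 0.00403). PTX3 (2.48 ± 0.19), NFKBIA (1.27 ± 0.10), ICAM1 (1.21 ± 0.10) and TNFAIP2 (1.39 ± 0.12) each had an edgeR adjusted p of 1.78e-05. CSF2 (2.49, edgeR adjusted p = 0.0987, 1.33e-06 with the replicate block) and IL1B (1.59, 0.624 and 2.23e-06) passed only with the block when all 16 libraries were kept. The test called 65 genes, 64 up and 1 down, and 486 with the block, 410 up and 76 down. All 17 called genes that the rule took by size, by p or as sentinels moved the same way in all 4 numbers. In number 2, IFIT2 was 9.24 CPM in MV and 9.36 in HDM+MV, OASL 3.33 and 4.14, and CXCL10 0.115 and 1.87. IFIT2 thus hardly differed there, while in number 20 it was 4.65 and 169.3 CPM. The count fell to 33 without MV 20, 38 without MV 21, 38 without MV 28, 43 without HDM+MV 21 and 42 without HDM+MV 28.

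With microvesicles present in both groups, 15 of 23 NF-kB targets rose with HDM, 20 adjusted over the list alone, at a median of 0.98 (camera adjusted p = 7.67e-152). Of the inflammatory genes 8 of 27 rose, 18 adjusted over the list alone, at a median of 1.60 (camera adjusted p = 5.85e-63). Of 31 interferon-stimulated genes, 5 rose, 12 adjusted over the list alone, IFIT2 among them, at a median of 0.41 (camera adjusted p = 4.12e-22, 0.0256 with an estimated correlation, 0.108 with that and the replicate block). Immediate early genes (1 up, 5 adjusted over the list alone, camera adjusted p = 4.84e-09) and EGFR feedback genes with EREG at 1.09 ± 0.15 (2 and 4, 9.32e-09) were higher. So were signalling brakes (3 and 4, 7.62e-10), p53 targets (1 and 4, 0.000206) and alarmins (0 and 1, 0.00145), and these 5 calls held with an estimated correlation. Oxidative stress genes with SLC7A11 (0.45 ± 0.06) were higher (1 and 1, camera adjusted p = 2.49e-05, 0.0743 with an estimated correlation, 0.0127 with that and the block). So were glucocorticoid-responsive genes (1 up, 1 up and 1 down adjusted over the list alone, 0.0286 and 0.0591, and 0.0333 with that and the block), prostaglandin genes (0 and 0, 0.0492 and 0.08, and 0.0392) and unfolded protein response genes (1 and 2, 0.0242 and 0.41). Actin genes were lower in 19 of 21 members at a median of -0.12 (0 and 0, camera adjusted p = 2.49e-05, 0.08 with an estimated correlation, 0.00473 with that and the block). The phagocytosis and engulfment list, to which AXL belongs, did not pass (median -0.02, camera adjusted p = 0.22). With the block, junctions passed as higher (0.0211, 0.423 with an estimated correlation), and cell cycle genes (0.0183 and 0.236), TGF-beta targets (0.0198 and 0.397) and ribosomal proteins (0.0198 and 0.607) as lower.

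Several of these calls ended when single libraries were left out, in fits without the replicate block. AXL (chromosome 19, 41725104 to 41767672; -0.26 ± 0.05, edgeR adjusted p = 0.0327) lost its call without Control 28, HDM 28, any MV library, or HDM+MV 20, 21 or 28 (adjusted p = 0.0522 to 0.112). IL6 (2.60 ± 0.46, edgeR adjusted p = 0.0165) lost it without MV 20 (0.0756), MV 21 (0.0582) or HDM+MV 28 (0.0612), and IFIT2 (3.84 ± 0.69, edgeR adjusted p = 0.018) without MV 20 (0.0876), MV 21 (0.0895) or MV 28 (0.0899). Without any 1 of these 3 MV libraries, the other 4 interferon-stimulated genes called, CXCL10, OASL, IRF1 and DDX58, lost their edgeR calls too (adjusted p = 0.0809 to 0.212), which leaves 0 of the 5. CXCL10 and OASL also lost them without MV 2, any Control library, HDM 2 or 28, or HDM+MV 20, 21 or 28 (0.0617 to 0.163). DDX58 did so without the same libraries apart from HDM 2 (0.0639 to 0.145), and IRF1 without Control 28, HDM 28, or HDM+MV 20 or 21 (0.0522 to 0.101). The p53 target called, TNFRSF10B, lost its call when any of 14 libraries was left out, all except Control 2 and HDM 2 (0.0507 to 0.179). NR4A3, the immediate early gene called, lost it without HDM 28, MV 2, 21 or 28, or HDM+MV 2, 21 or 28 (0.0571 to 0.145), and HBEGF of the EGFR list without MV 2, 21 or 28 or HDM+MV 20, 21 or 28 (0.0517 to 0.127). In these fits the log2 fold change was -0.28 to -0.23 for AXL, 2.33 to 2.42 for IL6, 3.69 to 3.78 for IFIT2, 3.24 to 5.27 for CXCL10, 2.41 to 3.64 for OASL, 1.40 to 1.86 for DDX58 and 0.78 to 0.96 for IRF1. It was 0.32 to 0.43 for TNFRSF10B, 2.08 to 2.44 for NR4A3 and 1.23 to 1.44 for HBEGF. All 10 passed in edgeR with the block (adjusted p = 3.17e-08 for IL6 to 0.00619 for NR4A3). CEBPB, the unfolded protein response gene called, lost its edgeR call without Control 21 or 28, HDM 28, any MV library, or HDM+MV 2, 21 or 28. Its adjusted p was then 0.0632 to 0.17 and its log2 fold change 0.59 to 0.71, and it passed with the block. Camera calls ended for glucocorticoid-responsive genes without MV 2, 20 or 21 or HDM+MV 2 or 28 (0.053 to 0.0946). They ended for prostaglandin genes without MV 2 (0.202), MV 20 (0.0712), HDM+MV 21 (0.0835) or 28 (0.0766), and for unfolded protein response genes without MV 2 (0.257), MV 21 (0.0798) or HDM+MV 2 (0.176).

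**Figure D4:**
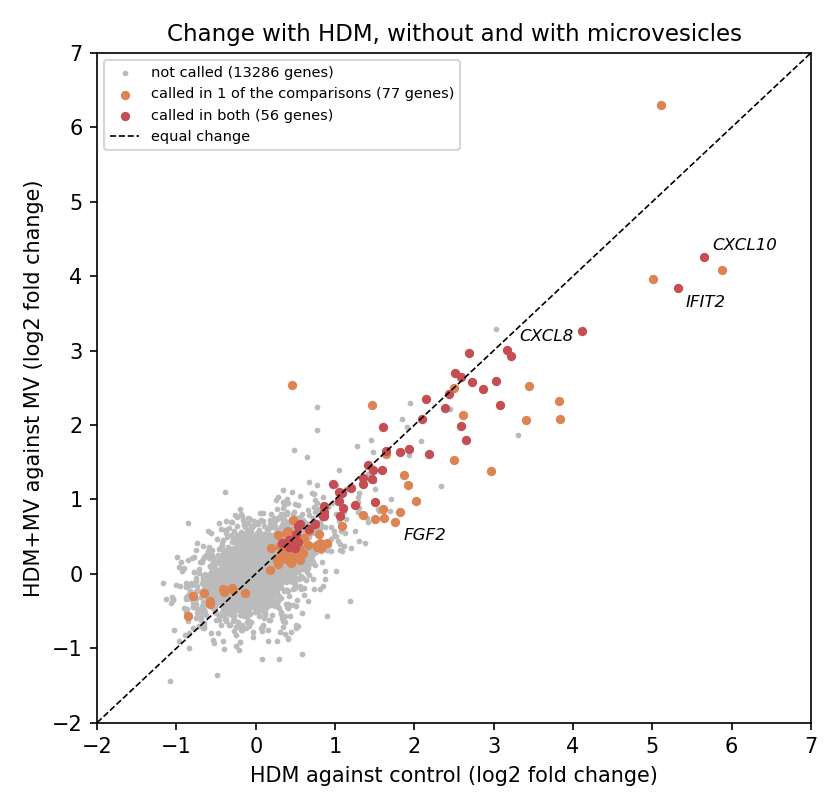
Log2 fold change of each of 13419 genes with HDM without microvesicles (horizontal) and with them (vertical), coloured by whether edgeR called the gene in both comparisons (56 genes), in 1 of them (77) or in neither (13286). Points below the dashed line of equal change, such as IFIT2 and FGF2, have a smaller fold change with microvesicles, a difference that passed its test for FGF2 only with the block and for IFIT2 in neither fit.

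The HDM effects without and with microvesicles, which share no library, correlated across 13419 genes (Pearson r 0.714, Spearman rho 0.504), where genes are not independent replicates. Of the 124 and 65 genes called, 56 were shared, all up, where independent lists would share 0.548. Without MV 2 the correlation was 0.576. The microvesicle effects without and with HDM correlated at r 0.0497 and rho 0.0228 across the same genes.

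The interaction tests whether the HDM effect differed with microvesicles. FGF2 had the smallest p: its HDM effect with microvesicles differed from that without by -1.06 ± 0.27 (log2, n = 4 per group, edgeR adjusted p = 1), and by -1.03 ± 0.12 with the replicate block (adjusted p = 0.00177). RGMB (chromosome 5, 98104999 to 98132198), which encodes a co-receptor for bone morphogenetic proteins and was chosen after its values were seen, passed only with the block (-0.48 ± 0.07, edgeR adjusted p = 0.00985). Both calls ended when the libraries numbered 2 were left out of the blocked fit, which then called 0 genes (FGF2 adjusted p = 0.117 by edgeR). KLF4 (-0.87 ± 0.26), FOS (0.58 ± 0.17), CPEB2 (-0.39 ± 0.12) and BLNK (1.53 ± 0.47) followed FGF2 by p and did not pass in either fit. CXCL8 (-0.16 ± 0.46), IL6 (-0.43 ± 0.62) and TNFAIP3 (-0.60 ± 0.41) did not pass, so a smaller rise of these genes with microvesicles was not shown.

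For the interaction, edgeR called 0 genes without the block and 2 with it, FGF2 and RGMB, with 92 and 481 genes at an unadjusted p under 0.05. The DESeq2 Wald test and limma-voom called 0, and DESeq2 with the block 4, which were FGF2, RGMB, CYR61 and LOC100996693, the last 3 chosen after their values were seen. For LOC100996693 the log2 fold change was 37.3 ± 6.04, too extreme to be read as the size of an effect. By camera the interaction was negative for interferon-stimulated genes (median -0.13, adjusted p = 3.77e-05, 0.556 with an estimated correlation) and TGF-beta targets (-0.209, 0.00306 and 0.536). It was also negative for NF-kB targets (-0.08, 0.00883 and 0.498), immediate early genes (-0.116, 0.00883 and 0.495) and actin genes (-0.077, 0.0117 and 0.556). With the block it was positive for glucocorticoid-responsive genes (0.000494, 0.0795 with an estimated correlation). The fry test called 0 lists without the block. In each of the 5 lists called negative 0 members passed, and adjusted over the list alone 1 immediate early gene was up and 1 down. The calls ended for interferon-stimulated genes without MV 2 (0.0605) and for TGF-beta targets without Control 2 (0.129), MV 20 (0.183) or HDM+MV 2 (0.0854). They ended for NF-kB targets without Control 21 (0.397), HDM 20 (0.0519), MV 28 (0.157) or HDM+MV 2 (0.117), and for immediate early genes without Control 2 (0.0559), HDM 2 (0.0547), HDM 28 (0.0926), MV 28 (0.0887) or HDM+MV 2 (0.117). For actin genes they ended without Control 28 (0.409), HDM 2 (0.253), HDM 20 (0.0663), MV 2 (0.103), MV 20 (0.183), MV 21 (0.0519) or HDM+MV 28 (0.457).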

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

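The counts over other splits of the samples were chosen after the results were seen, as was the set of genes in the depth test, and the other 2 tests of why genes raised by HDM lay lower with microvesicles were written before their results were seen.

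In 9 of 332 checks (2.71%), a single library lay far from the other 3 of its group, where chance gives about 1 in 20. The mean log2 CPM of immediate early genes was 4.31 in Control 28 against 4.14 to 4.16 in the other Control libraries, and that of actin genes was 7.6 in HDM+MV 28 against 7.79 to 7.81. Interferon-stimulated IFIT3 was at 24.8 CPM in Control 2 against 12.7 to 14.5, the receptor gene HCAR2 at 1.36 CPM in Control 20 against 0.564 to 0.667, and CYB561D1 at 16 CPM in HDM+MV 28 against 17.4 to 17.5. TNFAIP3 was at 84.9 CPM in HDM 2 against 153 to 163, and PTGS2 at 1.33 CPM in the same library against 7.87 to 8.76. C15orf61 was at 1.76 CPM in HDM+MV 2 against 2.1 to 2.17, and KLF4 at 23.4 CPM in HDM 21 against 43.5 to 45.4.

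FGF2 (-1.03) and RGMB (-0.48) were the genes whose HDM effect differed between cells with and without microvesicles in the test of the interaction with the replicate block (edgeR adjusted p = 0.00177 and 0.00985). FGF2 was lower in HDM+MV than in HDM in all 4 numbers. Neither passed without the block, and over all alternatives the adjusted p of FGF2 ran from 7.21e-13 to 1, with 0.117 when the libraries numbered 2 were left out of the blocked fit. That fit called 0 genes for the interaction, so RGMB lost its call as well, and 14 of 100 exchanges of the label, the real one included, gave as many genes (below). By camera without the block, the interaction also differed for NF-kB targets (median -0.08), immediate early genes (-0.116), interferon-stimulated genes (-0.13), TGF-beta targets (-0.209) and actin genes (-0.077), and for all 5 lists the call ended with an estimated correlation.

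Genes raised by HDM stood lower in HDM+MV than in HDM. Of the 623 genes raised by HDM against control with the block, 579 (92.9%) were lower in HDM+MV on average. Their median log2 differences were -0.028, -0.165, -0.15 and -0.101 in numbers 2, 20, 21 and 28, and over all 13419 genes the medians were 0.017, 0.001, -0.001 and -0.007. A single smaller share of the HDM response, the same for every gene, was tested as the whole cause. A share of 0.685, fitted on all 848 genes called, 225 of them lowered by HDM, left 12 genes departing from it. Of these 9 were lower, among them FGF2 at -0.69, CYR61 at -0.54 and RGMB at -0.28, and 3 were higher, CYP1B1 at 0.30 and, both lowered by HDM, DDIT4 at 0.30 and TOB1 at 0.20. The 848 genes were chosen with the same HDM libraries, and the fit takes the numbers of MV 20 and MV 21 as labelled. The departures therefore cannot decide whether a single share is the whole cause.

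The choice of the genes stays open for part of this pattern. Picking genes for high values in the HDM libraries makes HDM+MV look lower by itself. The 410 genes chosen instead by their rise in HDM+MV against MV had medians of 0.035, -0.121, -0.111 and -0.053, so that their median showed no shortfall in number 2. Because that choice favours high values in HDM+MV, a set that favours neither was examined as well: 1117 genes raised in both HDM groups against both others had medians of 0.022, -0.116, -0.114 and -0.044. Depth stays open too. The depth test as first written used the 623 genes, whose medians were below 0 in all 4 numbers, but their choice lowers HDM+MV in every number, so that it excluded nothing. The HDM+MV libraries had 0.907, 1.31, 1.12 and 0.865 times the counts of their HDM partners, and in this last set the shortfall was largest in numbers 20 and 21, where HDM+MV was deeper, but was also present in number 28, where it was not, and 4 numbers are too few to decide. A weaker epithelial response to HDM in the presence of microvesicles may account for the shortfall, as 1 hypothesis among these. In number 2 the last 2 sets had medians above 0 (highest 0.035). The shortfall was there in the inflammatory list (mean log2 CPM 3.19 in HDM 2 and 2.75 in HDM+MV 2), the NF-kB list (5.28 and 5.01) and immediate early genes (4.71 and 4.35). Interferon-stimulated genes (4.37 and 3.36) were in HDM+MV 2 below Control 2 (3.44) and above MV 2 (3.08). In number 21 that list was alike in HDM and HDM+MV (3.71 in both). TNFAIP3 and IL6 were lower in all 4 numbers. So were FGF2 and KLF4, but these were named for their small p in this same comparison. Signalling brakes (5.11 in HDM 2 and 4.94 in HDM+MV 2), p53 targets (4.91 and 4.79) and, slightly, heat shock genes (7.80 and 7.78) were lower as well. The other lists raised by HDM were higher in HDM+MV 2 than in HDM 2: EGFR feedback genes (5.68 in HDM 2 and 5.80 in HDM+MV 2), prostaglandin genes (2.98 and 3.13), oxidative stress genes (6.51 and 6.55) and alarmins (3.86 and 3.87). Unequal HDM doses or handling between the HDM and HDM+MV cultures would look the same and were not tested.

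Other splits of the same libraries were counted for each result. Because the numbers pair the samples, the splits to compare with are the 8 that part all 4 pairs, and these are too few for a share under 0.05. Without the block, the real and highest other counts among the 8 were 124 and 0 for HDM against control, 34 and 0 for HDM+MV against control, and 65 and 0 for HDM+MV against MV. With the block, they were 848 and 0 for HDM against control (1 of 8), 356 and 0 for HDM+MV against control (1 of 8), 30 and 0 for HDM+MV against HDM (1 of 8), and 486 and 0 for HDM+MV against MV (1 of 8). For MV against control they were 0 and 0 (8 of 8).

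Over all 35 splits, which ignore the pairs, 2 gave as many as the 124 genes of HDM against control, with a highest other of 1576. That split set numbers 2 and 28 of both groups against 20 and 21, parting none of the pairs, where the real split parts all 4, and it points to a structure of the samples by number. HDM+MV against MV was alike: 65 genes, 2 of 35 splits, and a highest other of 2201 from the same division of numbers. For HDM+MV against control, 34 genes compared with a highest other of 0 (1 of 35). Since the 35 splits ignore the pairs, these counts neither exclude chance nor favour it. With a real count of 0, every split gives as many, so the 35 of 35 for MV against control (highest other 0) and for HDM+MV against HDM (highest other 2) say nothing about chance.

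For the interaction, 100 drawn exchanges of the microvesicle label within numbers were counted. Without the block the real count was 0 (highest other 0, 100 of 100), which again says nothing about chance. With the block, 2 genes (FGF2 and RGMB) compared with a highest other of 901 (14 of 100), so chance could not be excluded. The exchange that gave 901 turned the label around in numbers 20, 21 and 28 of Control and MV and in numbers 2 and 28 of HDM and HDM+MV, and points to a structure of the samples.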

How the results depend on the processing

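The alternatives that exchanged the numbers of MV 20 and MV 21, left out the libraries numbered 2, or left out MV 20 and MV 21 were chosen after seeing the data, and the others were planned.

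The replicate block raised the number of genes called by edgeR from 124 to 848 for HDM against control, 34 to 356 for HDM+MV against control, 0 to 30 for HDM+MV against HDM, 65 to 486 for HDM+MV against MV, and 0 to 2 for the interaction. DESeq2 with the block called 814, 374, 44, 498 and 4 genes in the same order, and 1 for MV against control. Exchanging the numbers of MV 20 and MV 21 within the block gave 1263, 581, 79 and 777 for the first 4 of these (chosen after their values were seen). The blocked standard errors were smaller (median 0.0739 to 0.075 against 0.121 to 0.122), since the block removes differences between numbers. Of the named genes in the 6 comparisons, 236 results had the same call and 72 passed with the block only, and the 59 list calls kept their direction and call.

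The DESeq2 Wald test called more genes: 229 for HDM against control, 95 for HDM+MV against control, 5 for HDM+MV against HDM and 123 for HDM+MV against MV. The cause was not tested. Fits of only the groups compared called fewer, 72, 12 and 27 for HDM against control, HDM+MV against control and HDM+MV against MV, with fewer samples to estimate the spread. DESeq2 size factors, limma-voom, limma on the normalized counts, no filter and the 1 CPM filter moved no count by more than 1.5 times (118 to 125 genes for HDM against control). No named gene that was called reversed under any alternative.

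Leaving out the libraries numbered 2 in the blocked fit gave 609, 206, 20, 324 and 0 genes for HDM against control, HDM+MV against control, HDM+MV against HDM, HDM+MV against MV and the interaction, with fewer samples and number 2 gone. Leaving out MV 20 and MV 21 gave 13 for HDM+MV against MV, where MV then had 2 libraries.

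Leaving out each library in turn was done without the block only. The counts ran from 87 (without Control 28) to 138 (without MV 2) for HDM against control, 0 to 0 for MV against control, and 24 to 42 for HDM+MV against control. They ran from 0 to 2 for HDM+MV against HDM (2 without HDM 21), 33 to 65 for HDM+MV against MV and 0 to 0 for the interaction. The correlation of the HDM effects without and with microvesicles ran from 0.576 (without MV 2) to 0.693. The direction of 3 lists in MV against control reversed. The camera adjusted p ran from 0.000129 to 0.977 (reversed without MV 2) for EGFR ligands and MAPK feedback, from 1.11e-05 to 0.649 (reversed without Control 2) for interferon-stimulated genes, and from 3.7e-06 to 0.992 (reversed without Control 28) for cytosolic ribosomal proteins. In mean log2 CPM, MV 2 (5.31) and Control 2 (5.33) were the lowest of their groups for EGFR genes. Control 2 (3.44) and MV 2 (3.08) were the highest for interferon-stimulated genes, as were Control 28 (10.17) and MV 28 (10.12) for ribosomal proteins. Each reversal thus came when a library at the end of its group was left out and its same-numbered partner was kept. Leaving out both was not tested for the lists.

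Of 59 list results called by camera, 23 kept their call with an estimated correlation and 26 with fry. On simulated counts with nothing planted, camera at the preset correlation called 1 list and with an estimated correlation 0. Genes were drawn independently there, in random lists, so this cannot rank the 2 settings for lists of genes that move together. Calls that ended with the estimate depend on the correlation assumed. Depth limits which genes could be tested: those under about 0.552 CPM were mostly filtered out, and changes in them were not detectable at this depth.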

Other observations

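The exchange of 2 microvesicle libraries, the comparisons between replicate numbers and the fit without number 2 were chosen after the results or the data were seen.

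The replicate numbers separated more genes than any of the 6 comparisons. In an edgeR test of all 4 numbers together (4 libraries per number, over all 4 groups), 7520 of 13419 genes differed among numbers. With each number set against the mean of the other 3 in separate edgeR tests, 7232 genes differed for number 2. In number 2 the imprinted gene PEG10 was at 4060 ± 578 CPM against 439 in the others (log2 fold change 3.25 ± 0.05, edgeR adjusted p = 6.42e-17). The chitinase-like gene CHI3L1 was at 52.7 ± 4.64 against 5.37 CPM (3.43 ± 0.08, edgeR adjusted p = 4.2e-15), and the retinol enzyme gene DHRS3 was lower (-3.60 ± 0.26, adjusted p = 6.4e-09). The matrix gene TNC was higher in number 20 (465 ± 112 against 217 CPM, edgeR adjusted p = 2.09e-10). By edgeR, the stress gene HMOX1 was higher in number 28 (208 ± 44.9 against 134 CPM, adjusted p = 2.59e-05). Number 2 is part of the mean that each of the other numbers was set against, so its own differences enter those contrasts.

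By list, epithelial junction genes differed between numbers. Of 20, 16 were lower in number 2 at a median of -0.63 (camera adjusted p = 1.34e-10, 0.312 with an estimated correlation). In the same way 15 were higher in number 20 at 0.50 (1.8e-21 and 0.0551), 14 were higher in number 21 at 0.42 (3.35e-17 and 0.103), and 12 were lower in number 28 at -0.24 (1.48e-16 and 0.0392). Cell cycle genes were higher in number 2, 22 of 29 at a median of 0.24 (camera adjusted p = 0.00049, 0.312 with an estimated correlation). In number 28, oxidative stress genes were higher at a median of 0.15 (7.11e-10 and 0.00993) and actin genes lower at -0.12 (1.34e-10 and 0.00836). The labels do not say what a number stands for, so passage, day and RNA kit could each follow it. Leaving out number 2 moved the count for HDM against control from 124 to 178.

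The MV libraries 20 and 21 each deviated more like the other number: MV 20 correlated at 0.652 with number 21 and 0.428 with 20 across genes, and MV 21 at 0.59 with number 20 and 0.449 with 21. Numbers too alike to be told apart are argued against, since the same exchange raised the residual sum of squares in each of the other 3 groups (by 2.54%, 4.06% and 4.29%). An exchange of the numbers 20 and 21 within MV is a candidate explanation. It changed the residual sum of squares by -10.1%, the lowest of the 24 orders of the MV numbers. The difference between 20 and 21 ran opposite in MV (r -0.348 to -0.238 with the other groups, against 0.231 to 0.317 among them, across 13419 genes that are not independent replicates). The change within MV and these correlations come from the same deviations that raised the question, so they are not separate evidence for an exchange. No biological explanation was tested. The exchange leaves the fold changes and calls without the block as they are, since the group of both libraries is MV either way. Directions per number, splits by pairs and the paired marker test below use the numbers as labelled.

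Vesicles carry RNA, so transcripts of the macrophages might appear in libraries that received them. The summed level of 24 macrophage markers that the cell line hardly expresses was 1.22 ± 0.29 CPM in the 8 libraries with vesicles and 1.02 ± 0.13 in the 8 without. The ratio was 1.17 (95% interval 0.926 to 1.48, higher in 7 of 8 pairs, exact paired two-sided permutation p = 0.133). The most abundant markers had few reads in both, with 69 reads of CSF1R with vesicles and 54 without, 50 and 45 of LYZ, 22 and 8 of MARCO, and 12 and 14 of FCER1G. With 13 to 31 reads of all markers per library, carried RNA and none cannot be told apart, and RNA of a species other than human would map poorly.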
